A study of Mus musculus with 12 samples.

How the data were processed

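Polyadenylated RNA of 12 mouse libraries was sequenced from a stranded mRNA kit. The sample labels call all of them hepatocytes purified on a Percoll gradient, while the series design calls the TAA and control libraries livers, and they are called livers here. The hepatocytes came from a line with floxed Lats1 and Lats2 alleles, all titled wild type, and the livers from CD-1 mice. Whether Cre was present, which bears on Lats1, Lats2 and YAP/TAZ target values, is not given in the sources used here. Groups and replicate numbers were taken from sample titles. Replicates differed by more than sampling noise in every group, so none was counted as a duplicate.

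The authors deposited a table of raw counts per gene for 41128 genes, which was the input of every main test. They also deposited a table of RPM values for 17311 genes. Each is a count scaled by the library total of the count table: 100% of them gave whole counts, and the genes kept have a summed count of at least 13. Per the submitters' processing notes, STAR and DESeq2 were used with the builds mm10 and GRCm38, without versions or roles. The gene annotation and the strand setting used in counting are not given in the sources used here, so overlapping and antisense genes, and members of near-identical families such as Cyp2c, Cyp3a, Cyp2b, Mup, Serpina3, Saa and Gsta, may share reads. Of the IDs in the count table, 40254 (97.9%) were found in GENCODE mouse release M21 on GRCm38, which gave positions, exon overlaps and symbols, and 75 symbols belong to more than 1 gene.

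Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM, filterByExpr with a minimum count of 10 and total of 15, quasi-likelihood F test, two-sided, Benjamini-Hochberg adjustment, threshold 0.05, prior count 0.125). The 6 hepatocyte libraries formed 1 fit (13442 genes tested) and the 6 liver libraries another (13497 genes), since stock differs and preparation may differ. TMM factors ran from 0.750 to 1.31. The biological coefficient of variation was 0.358 in hepatocytes and 0.188 in livers. In every library 3 counts, the floor of detection, correspond to between 0.162 and 0.311 RPM, for counting error only. Alternatives were RLE, upper-quartile and no factors, DESeq2 1.42.0, no count filter or a filter of 50 counts, an adjusted p under 0.01, a 2-fold change, legacy and robust dispersion, all 12 libraries or only 4 in 1 fit, the replicate number as a block, limma 3.58.1 on log2(RPM + 0.5) and log2(RPM + 0.1), and each library left out.

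Groups, comparisons, tests, alternatives, 29 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison (27 lists in hepatocytes and 26 in livers). Beside it stand camera with an estimated correlation, under which no list passed in any comparison, and fry, which asks only whether a list moves on balance one way. Camera called 15, 20, 20 and 10 lists in the 4 comparisons and fry 10, 22, 24 and 1. A median is given also with genes absent from a group set at a bound of 3 counts over that group.

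Named genes are Yap1, Wwtr1, Ctgf, Cyr61, Ankrd1, Lats1, Lats2, Notch1, Akt1 and Cyp2e1 in the 3 comparisons with an untreated group. To these were added the 4 largest rises and falls among called genes with a mean of at least 10 CPM in the higher group, at least 4 counts over the lower group and no overlap between the groups, leaving out predicted, Rik, pseudogene and clone names, also RP2, CH and dotted ones. The 4 YAP/TAZ targets and the 2 members of each other primary list with the smallest p were named too, as were 2 of each secondary list with at least 50% of its members called. Between the times, 2 rises, 2 falls and 1 member of each list with at least 50% called were named. Other sex-linked and acinar genes were named after their values were seen. Of the genes that the rule names, 3 are not reported.

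Overlaps of calls were set beside those of independent lists. For the 2 TAA times, 20 simulated pairs of unchanged groups shared the controls. EdgeR, DESeq2 and camera against an untreated group were run on simulated counts with 200 changed genes in 5 draws. Of 2-fold and 4-fold changes edgeR found 7.20% and 57.2% in the peritumoral, 27.6% and 72.8% in the 24 h and 30.4% and 73.4% in the 48 h comparison, with 6.32%, 6.73% and 7.68% of calls false, and 26.1%, 16.1% and 17.6% of those by DESeq2. Camera found a YAP/TAZ list raised 2-fold in 5 of 5 draws in all 3. It called 3 of 130, 0 of 125 and 4 of 125 unchanged lists. In the data more genes changed and may vary together, so rates may differ.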

Results

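Of 12 libraries in 5 groups, 6 held hepatocytes purified on a density gradient. Of these, 3 came from untreated animals and 3, labelled peritumoral, from tissue around liver tumours grown for 8 weeks. Every label gives an age of 8 weeks, but mice were injected at that age, so the peritumoral group may be older. The tumours were started by hydrodynamic injection of plasmids for the SB11 transposase (1 µg), the active part of Notch (20 µg) and Akt (4 µg). The other 6 libraries came from mice of another stock: 2 controls, 2 taken 24 h and 2 taken 48 h after thioacetamide (TAA). Cyp2e1 activates this toxin in hepatocytes around the central vein. Total counts ran from 16228747 to 18522324 in hepatocytes and from 9640845 to 13692235 in livers. The study's title names YAP and TAZ, the transcriptional effectors of the Hippo growth-control pathway. Levels are TMM-scaled CPM as mean ± SD, fold changes are on the log2 scale ± SE, and adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of lists from camera. Where 2 counts are adjusted over a list alone, higher genes come first. No label says libraries of a group came from separate animals, so p-values measure only the spread between libraries. It may be technical, but sex transcripts mark peritumoral replicate 2 as another animal.

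Peritumoral hepatocytes held more transcript of YAP/TAZ target genes, of bile duct, stromal and endothelial genes, and of cell cycle genes than untreated hepatocytes (n = 3 each). Ctgf, a classic YAP/TAZ target, stood at 53.4 ± 7.92 against 8.87 ± 2.33 CPM, a log2 fold change of 2.59 ± 0.25 (adjusted p = 0.00285). Cyr61, a relative of Ctgf, rose by 2.05 ± 0.34 to 149 CPM, and Ankrd1, an ankyrin repeat protein, by 2.40 ± 0.51 to 5.37 CPM. Krt19, a keratin of bile ducts, stood at 31.7 ± 27.5 against 0.685 ± 0.310 CPM. In all, 2560 of 13442 tested genes were higher and 1370 lower at an adjusted p under 0.05, of which 2423 and 371 moved at least 2-fold.

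Of 20 YAP/TAZ target genes, 15 rose and 5 did not pass (17 adjusted over the list alone). The median was 2.49 (adjusted p = 7.0e-11, or p = 0.107 with estimated correlation). Igfbp3, an insulin-like growth factor binding protein, went from 6.05 to 50.8 CPM. Ccdc80, a matrix protein, rose by 4.57 ± 0.50 and the RNA-binding protein gene Rbms3 by 3.53 ± 0.37. On the GRCm38 genome, Ctgf is ENSMUSG00000019997, chromosome 10, positions 24595442 to 24598683, plus strand, and Cyr61 is ENSMUSG00000028195, chromosome 3, positions 145646976 to 145649981, minus strand. Ankrd1 is ENSMUSG00000024803, chromosome 19, positions 36111961 to 36120099, minus strand. All 3 are protein-coding, and exons of Ctgf overlap an antisense transcript over 23.2% of their length, while the strand used in counting is not stated. Yap1 was lower, at 67.5 ± 14.6 against 106 ± 8.54 CPM (adjusted p = 0.0430), and Wwtr1, the gene of TAZ, higher, at 35.2 ± 3.90 against 20.9 ± 2.93 CPM (adjusted p = 0.0221). The call on Yap1 was lost without untreated replicate 1, 2 or 3 or peritumoral replicate 2 or 3 (adjusted p = 0.0587 to 0.184). That on Wwtr1 was lost without untreated replicate 1 or 2 or peritumoral replicate 2 or 3 (adjusted p = 0.0505 to 0.0837), and that on Ankrd1 without untreated replicate 1 (adjusted p = 0.0710). The genes of the upstream kinases did not pass, at -0.23 ± 0.16 for Lats1 and 0.41 ± 0.17 for Lats2. Of 22 Hippo pathway components, 7 rose, 1 fell and 14 did not pass (7 and 1 adjusted over the list alone). The median was 0.36 (adjusted p = 0.107). The angiomotin family gene Amotl1 rose by 2.50 ± 0.27 and the kinase gene Map4k4 by 2.77 ± 0.45. Without untreated replicate 1 or 2, only 2 Hippo components rose.

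**Figure D1:**
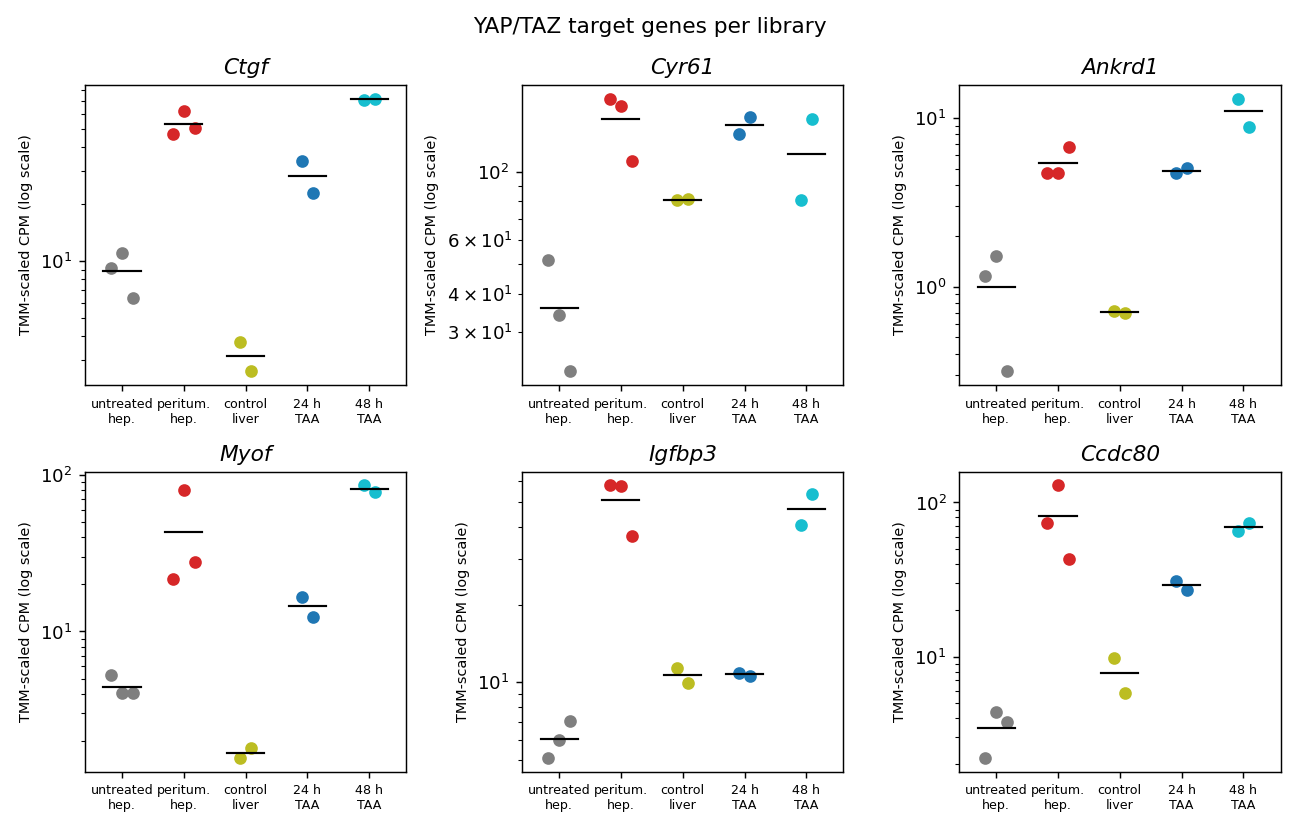
TMM-scaled CPM (log axis) of 6 YAP/TAZ target genes in each library, with 1 point per library and a line at the group mean. Ctgf averages 8.87 CPM in untreated and 53.4 CPM in peritumoral hepatocytes.

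Markers of other liver cells moved with the YAP/TAZ target genes. All 18 endothelial genes rose (18 adjusted over the list alone). The median was 2.08 (adjusted p = 2.3e-12, or p = 0.452 with estimated correlation). Stab2, a scavenger receptor of sinusoidal endothelium, stood at 179.8 ± 42.4 against 40.3 ± 6.42 CPM, and the endothelial phosphatase gene Ptprb rose by 2.02 ± 0.25. Of 19 stellate cell and matrix genes, 16 rose and 3 did not pass (17 adjusted over the list alone). The median was 3.25 (adjusted p = 9.1e-15, or p = 0.0782 with estimated correlation). Dcn, a matrix proteoglycan, stood at 291 ± 69.1 against 30.6 ± 7.36 CPM, and the matrix gene Sparc rose by 3.69 ± 0.34. Of 19 macrophage genes, 14 rose and 5 did not pass (14 adjusted over the list alone). The median was 2.95 (adjusted p = 5.1e-09, or p = 0.452 with estimated correlation). The chemokine receptor gene Cx3cr1 rose by 2.82 ± 0.33 and the integrin gene Itgam by 3.61 ± 0.37, though 68.7% of the exon length of Itgam is shared with another gene. Summed macrophage markers took 629, 639.6 and 456 RPM in untreated and 2199, 3756 and 5973 RPM in peritumoral libraries. Of 10 neutrophil genes, 8 rose and 2 did not pass (9 adjusted over the list alone). The median was 2.72 (adjusted p = 0.000128, or p = 0.467 with estimated correlation). The granule genes Ngp and Ltf rose by 5.91 ± 0.77 and 6.11 ± 0.89 (7.05 without untreated replicate 2 and 8.11 without untreated replicate 1), and 4 and 5 neutrophil genes rose without untreated replicates 1 and 2 in turn. Of 3 lymphocyte genes, 1 rose and 2 did not pass (1 adjusted over the list alone). None of 5 red blood cell genes passed by edgeR, also unadjusted, or by DESeq2, and their median of 0.91 differed in sign from their test (adjusted p = 0.763). Without peritumoral replicate 1, 3 of 5 lymphocyte genes then tested rose, and without peritumoral replicate 2, 2 red blood cell genes.

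Bile duct genes had the highest median of the lists tested. Of 17 biliary and progenitor genes, 14 rose and 3 did not pass (15 adjusted over the list alone). The median was 5.37 (adjusted p = 1.6e-07, or p = 0.467 with estimated correlation). Krt19 rose by 5.51 ± 0.76 and the chloride channel gene Cftr by 8.52 ± 1.31 (6.34 without peritumoral replicate 2). Of 11 Notch pathway genes, 9 rose and 2 did not pass (9 adjusted over the list alone). The median was 2.29 (adjusted p = 0.000557, or p = 0.467 with estimated correlation). The Notch target gene Heyl rose by 7.06 ± 1.33 (4.90 without peritumoral replicate 2) and the glycosyltransferase gene Lfng by 2.29 ± 0.35. Without untreated replicate 1 or 2, only 2 Notch pathway genes passed, and Heyl lost its call (adjusted p = 0.0538 and 0.0581). Peritumoral replicate 2 stood apart: its biliary genes summed to 11238 RPM, against 1268 and 881 RPM in replicates 1 and 3. In untreated hepatocytes they summed to 71.7, 72.3 and 90.1 RPM. Notch1, part of which was injected, stood at 462 RPM in peritumoral replicate 2 and at 77.9 and 77.1 RPM in the others. Its rise of 3.002 ± 0.64, or 1.93 without peritumoral replicate 2, lost its call without untreated replicate 1 or 2 (adjusted p = 0.0654 and 0.0730). Akt1 did not pass, at 0.76 ± 0.33 (adjusted p = 0.126). Xist, the transcript of the inactive X chromosome, stood at 527 RPM in peritumoral replicate 2 and at most 0.183 RPM in the other hepatocyte libraries.

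**Figure D2:**
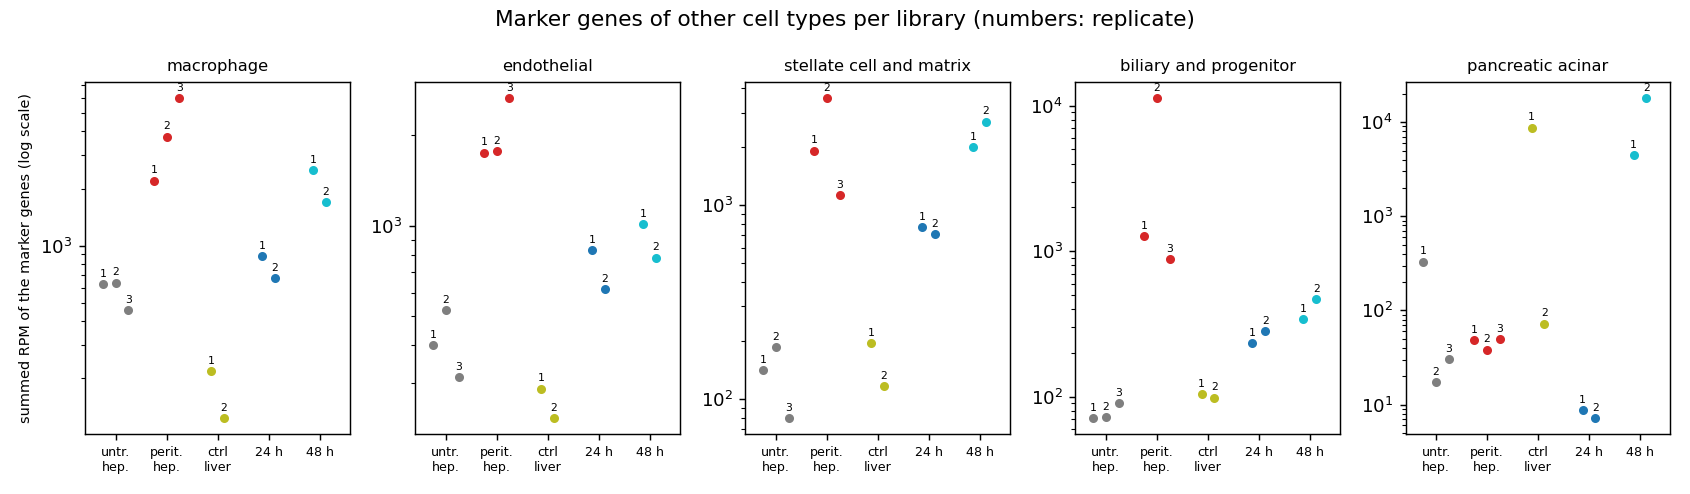
Summed RPM (log axis) of markers of macrophages, endothelium, stellate cells, bile ducts and pancreatic acinar cells in each library, with 1 point per library, numbered by replicate. Peritumoral replicate 2 lies highest for bile duct genes (11238 RPM).

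Among hepatocyte genes, Glul, the glutamine synthetase of cells next to the central vein, stood at 767 ± 114 against 80.4 ± 13.6 CPM. The pericentral cytochrome gene Cyp2c50 rose by 3.70 ± 0.36, with reads that relatives in its family may share, and Cyp2e1 did not pass, at 1.10 ± 0.48. Of 14 pericentral genes, 6 rose and 8 did not pass (6 adjusted over the list alone). The median was 1.40 (adjusted p = 0.000242, or p = 0.289 with estimated correlation). Of 15 periportal genes, 1 fell and 14 did not pass (none adjusted over the list alone). The median was -0.30 (adjusted p = 0.139). The urea cycle gene Arg1 fell by 1.03 ± 0.30, a call lost with any 1 of the 6 libraries left out (adjusted p = 0.0534 to 0.186), and Hsd17b6 did not pass, at -1.99 ± 0.80. The periportal list passed, downwards, without untreated replicate 1 or 2 (adjusted p = 0.0435 and 0.0201). Of 20 hepatocyte identity genes, 1 fell and 19 did not pass (none adjusted over the list alone). The median was -0.47 (adjusted p = 0.00981, or p = 0.637 with estimated correlation). Its call was lost without untreated replicate 3 or peritumoral replicate 2 (adjusted p = 0.0695 and 0.0686). Tdo2, a tryptophan-degrading enzyme, fell by 1.77 ± 0.43, a call lost without untreated replicate 1, 2 or 3 or peritumoral replicate 3 (adjusted p = 0.0503 to 0.0877), and Hnf4a, a master regulator of hepatocytes, stood at -0.78 ± 0.29 (adjusted p = 0.0856).

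Of 26 cell cycle genes, 13 rose and 13 did not pass (13 and 1 adjusted over the list alone). The median was 2.06 (adjusted p = 2.0e-06, or p = 0.475 with estimated correlation). The mitotic cyclin gene Ccnb1 rose by 5.13 ± 0.41, and Foxm1, a driver of mitotic genes, went from 0.971 to 10.8 CPM. Without untreated replicate 1, 7 cell cycle genes rose, and without untreated replicate 3, 2 fell. Of 15 immediate early and dissociation stress genes, 12 rose and 3 did not pass (14 adjusted over the list alone). The median was 1.62 (adjusted p = 4.2e-08, or p = 0.0782 with estimated correlation). The nuclear receptor gene Nr4a1 reached 203 ± 51.1 CPM and the AP-1 gene Junb rose by 1.71 ± 0.20, and 7 of the list rose without untreated replicate 1 or 2. Of 21 actin and dedifferentiation genes, 8 rose and 13 did not pass (9 and 2 adjusted over the list alone). The median was 0.98 (adjusted p = 0.0134, or p = 0.641 with estimated correlation). This call was lost without untreated replicate 3 or peritumoral replicate 2 (adjusted p = 0.519 and 0.0686). Without untreated replicate 1, 5 actin genes rose, and without untreated replicate 3, 5 fell. Of 17 endoplasmic reticulum stress genes, 1 rose, 4 fell and 12 did not pass (2 and 8 adjusted over the list alone). The median was -1.07 (adjusted p = 0.00501, or p = 0.615 with estimated correlation). Without peritumoral replicate 1, 7 of them fell, without peritumoral replicate 2, 1, and without untreated replicate 1 or 2 or peritumoral replicate 3 none passed by edgeR. Of 20 cholesterol synthesis genes, 2 fell and 18 did not pass (none adjusted over the list alone). The median was -0.46 (adjusted p = 0.00981, or p = 0.637 with estimated correlation). Without peritumoral replicate 2 the cholesterol call was lost (adjusted p = 0.104), and without untreated replicate 3, 4 of its genes fell, but fewer than 2 without untreated or peritumoral replicate 1 or 2.

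Of 22 acute phase genes, 3 rose and 19 did not pass (1 adjusted over the list alone). The median was 0.55 (adjusted p = 0.139). Socs3, a feedback inhibitor of cytokine signalling, rose by 1.77 ± 0.31 and the cytokine antagonist gene Il1rn by 1.93 ± 0.49, a call lost with any library but peritumoral replicate 1 left out (adjusted p = 0.0641 to 0.0871). The acute phase list passed without untreated replicate 3 (adjusted p = 0.00807), and without peritumoral replicate 1, 5 of its genes rose. Of 17 bile acid genes, 2 fell and 15 did not pass (2 adjusted over the list alone). The median was -0.16 (adjusted p = 0.207). Of 15 fatty acid synthesis genes, 1 fell and 14 did not pass (1 adjusted over the list alone). The median was -0.53 (adjusted p = 0.139). This list passed, downwards, without peritumoral replicate 3 (adjusted p = 0.0243). Of 17 fatty acid oxidation genes, 1 rose, 3 fell and 13 did not pass (none adjusted over the list alone). The median was -0.69 (adjusted p = 0.119). It passed without untreated replicate 2 or peritumoral replicate 3 (adjusted p = 0.0201 and 0.0293). Of 17 p53 response genes, 4 rose and 13 did not pass (4 adjusted over the list alone). The median was 0.46 (adjusted p = 0.130). Of them, 2 rose without untreated replicate 2. Of 23 interferon response genes, 5 rose and 18 did not pass (2 adjusted over the list alone). The median was 0.64 (adjusted p = 0.329). Interferon genes that rose numbered 2 without untreated replicate 1 or 3 or peritumoral replicate 3, 1 without untreated replicate 2, 3 without peritumoral replicate 1 and 8 without peritumoral replicate 2, when the list passed (adjusted p = 0.0117). Of 17 oxidative stress genes, 1 rose, 4 fell and 12 did not pass (1 and 4 adjusted over the list alone). The median was -0.44 (adjusted p = 0.118). That list passed without untreated replicate 1 or 3 (adjusted p = 0.0433 and 0.0404), and 2 of its genes fell without untreated replicate 1. Of 14 circadian clock genes, 2 fell and 12 did not pass (1 adjusted over the list alone). The median was -0.53 (adjusted p = 0.130). Fewer than 2 acute phase genes passed without untreated replicate 1 or 2 or peritumoral replicate 3, while fewer than 2 fatty acid oxidation genes fell with any library but peritumoral replicate 3 left out, fewer than 2 clock genes without untreated replicate 1 or 2 or peritumoral replicate 2 or 3, and fewer than 2 bile acid genes without untreated or peritumoral replicate 1 or 2.

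The largest rises among named genes were those of Cyp3a44, a cytochrome of female liver, at 9.84 ± 1.90, the serpin gene Serpina3c at 9.76 ± 2.29, the peptide transporter gene Slc15a2 at 9.33 ± 1.58 (7.04 without peritumoral replicate 2) and the glycoprotein gene Gp2 at 9.27 ± 2.31. Gp2 rose by 14.55 without untreated replicate 1 and 6.51 without peritumoral replicate 2. The calcium-binding protein gene S100g fell by 6.84 ± 0.43, the major urinary protein gene Mup21 by 5.36 ± 1.29, and the lipid droplet gene Cidec fell by 5.31 ± 1.10, while the epithelial gene Sprr1a fell by 4.96 ± 0.89. Without peritumoral replicate 1, Serpina3c stood at 8.46 and Mup21 at -7.03, Cyp3a44 at 8.66 without peritumoral replicate 3, and Slc15a2 at 10.71 without untreated replicate 3. Calls were lost on Cyp3a44 without untreated replicate 1 or 2 (adjusted p = 0.0550 to 0.0607), on Serpina3c without untreated replicate 1, 2 or 3 (0.0741 to 0.0899) and on Gp2 without untreated replicate 2 or 3 (0.0709 to 0.0777). Those on Mup21 were lost without untreated replicate 1, 2 or 3 or peritumoral replicate 3 (adjusted p = 0.0550 to 0.0757), and on Cidec without untreated replicate 1 or 2 or peritumoral replicate 3 (0.0506 to 0.0538). Cyp3a44, Serpina3c and Mup21 belong to families of near-identical genes, so their reads are uncertain. Cyp3a44 stood at 1.77, 165 and 294 RPM in peritumoral replicates 1 to 3, of which replicate 2 alone held Xist and no read of Ddx3y. None of 12 male-biased liver genes passed by edgeR, but 3 did at an unadjusted p under 0.05, 2 by DESeq2, none adjusted over the list alone, and 7 without peritumoral replicate 1. Their median was -2.14 (adjusted p = 0.00233, or p = 0.560 with estimated correlation). Of 5 female-biased liver genes, 3 rose and 2 did not pass (4 adjusted over the list alone). The median was 4.09 (adjusted p = 0.199). That list passed without untreated replicate 1 or 2 or peritumoral replicate 1 (adjusted p = 0.00892, 0.0240 and 2.6e-10), with 9 of 10 genes then tested rising in the last case and fewer than 2 in the others or without peritumoral replicate 3. Without peritumoral replicate 2 the male-biased median was -1.75 and the female-biased one 4.13. Cux2, a regulator of female liver genes, rose by 5.75 ± 1.48 (8.18 without untreated replicate 1), a call lost without untreated replicate 2 or 3 or peritumoral replicate 2 or 3 (adjusted p = 0.0525 to 0.102). None of 4 sex chromosome transcripts passed by edgeR, also unadjusted, or by DESeq2.

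Of the genes called in peritumoral hepatocytes, 65.1% were higher, or 92.7% without scaling factors and 80.1% with upper-quartile scaling, which shifted the median of all genes by 0.12 relative to TMM. The lower genes numbered 66 and 130 without untreated replicates 1 and 2 and 626 and 433 without peritumoral replicates 2 and 3, and the higher genes 1293 and 1364 without untreated replicates 1 and 2. Without peritumoral replicate 2 and untreated replicate 3 together, the libraries furthest from the others of their group (chi-squared per degree of freedom of 209 and 232, against 94.2 between the others, and of 133 and 137, against 16.9), 3106 genes were higher and 2382 lower.

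At 24 h after TAA, livers held more transcript of acute phase, interferon and actin genes and less of pericentral and bile acid genes than control livers (n = 2 each). Cyp2e1, the enzyme that activates TAA, was at 230.3 ± 28.2 against 5347 ± 1595 CPM, a log2 fold change of -4.54 ± 0.30 (adjusted p = 0.000393). Afp, the fetal serum protein, rose by 8.41 ± 0.54 to 453 ± 138 CPM. Anxa2, a membrane-binding annexin, went from 5.85 to 188 CPM, and Ctgf from 3.16 to 28.3 CPM, a rise of 3.16 ± 0.26. In all, 2877 of 13497 genes were higher and 2767 lower at an adjusted p under 0.05, of which 2002 and 1372 moved at least 2-fold.

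Of 21 YAP/TAZ target genes, 11 rose, 1 fell and 9 did not pass (11 and 1 adjusted over the list alone). The median was 1.16 (adjusted p = 0.000225, or p = 0.214 with estimated correlation). Of them, 7 rose without 24 h replicate 1, 24 h replicate 2 or control replicate 2. Myof, a membrane repair protein, rose by 3.11 ± 0.20 and Ankrd1 by 2.76 ± 0.32, while Nt5e, an ecto-enzyme that makes adenosine, fell by 1.58 ± 0.18. Cyr61 stood at 142 ± 13.1 against 81.0 ± 0.383 CPM, a call (adjusted p = 0.0461) that was lost without either 24 h or either control library (adjusted p = 0.116 to 0.170). Wwtr1 rose by 0.96 ± 0.16, and Yap1 at 0.12 ± 0.12, Lats1 at -0.060 ± 0.11 and Lats2 at 0.15 ± 0.19 did not pass. Lats1 turned positive with upper-quartile scaling (0.090) and Lats2 negative without control replicate 1 (-0.10), and 42.4% of the exon length of Lats2 is shared with another gene. Of 22 Hippo pathway components, 7 rose, 3 fell and 12 did not pass (7 and 3 adjusted over the list alone). The median was 0.14 (adjusted p = 0.287). Ajuba, an inhibitor of Lats kinases, rose by 1.77 ± 0.17 and Tead1, a DNA-binding partner of YAP, by 0.94 ± 0.15. Without 24 h replicate 1, 4 components rose and none fell by edgeR.

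Hepatocyte genes fell in both zones. Of 14 pericentral genes, 12 fell and 2 did not pass (13 adjusted over the list alone). The median was -2.92 (adjusted p = 1.2e-11, or p = 0.178 with estimated correlation). Cyp2c50 went from 531 to 28.9 CPM. Of 15 periportal genes, 10 fell and 5 did not pass (12 adjusted over the list alone). The median was -1.69 (adjusted p = 2.7e-06, or p = 0.178 with estimated correlation). The immunoglobulin receptor gene Pigr fell by 2.33 ± 0.17 and the urea cycle gene Asl stood at -2.24 ± 0.17. Of 20 hepatocyte identity genes, 14 fell and 6 did not pass (16 adjusted over the list alone). The median was -1.07 (adjusted p = 2.7e-06, or p = 0.245 with estimated correlation). The coagulation genes Proc and F9 stood at -1.45 ± 0.13 and -1.31 ± 0.12. Of 17 bile acid genes, 15 fell and 2 did not pass (15 adjusted over the list alone). The median was -2.44 (adjusted p = 2.9e-12, or p = 0.178 with estimated correlation). The export pump gene Abcb11 was at 143 ± 9.82 against 776 ± 31.0 CPM and the conjugating enzyme gene Baat at -2.05 ± 0.12. Of 17 fatty acid oxidation genes, 15 fell and 2 did not pass (16 adjusted over the list alone). The median was -1.52 (adjusted p = 2.0e-08, or p = 0.178 with estimated correlation). Among them were Cyp4a14 at -5.06 ± 0.44 and Acadm at -1.79 ± 0.17. Of 15 fatty acid synthesis genes, 8 fell and 7 did not pass (8 adjusted over the list alone). The median was -0.81 (adjusted p = 0.00106, or p = 0.404 with estimated correlation). The carboxylase gene Acacb stood at -2.03 ± 0.12 and the glucose-responsive regulator Mlxipl at -2.09 ± 0.18, and 5 fell without 24 h replicate 1. Of 20 cholesterol synthesis genes, 2 rose, 1 fell and 17 did not pass (none adjusted over the list alone). The median was 0.62 (adjusted p = 0.256). That list passed without control replicate 1 (adjusted p = 0.0209, 8 genes higher), and fewer than 2 were higher without 24 h replicate 1 or 2 or control replicate 2. Of 10 male-biased liver genes, 2 rose, 6 fell and 2 did not pass (3 and 6 adjusted over the list alone). The median was -1.70 (adjusted p = 0.0244, or p = 0.245 with estimated correlation). Of 12 female-biased liver genes, 11 fell and 1 did not pass (11 adjusted over the list alone). The median was -3.42 (adjusted p = 7.1e-08, or p = 0.214 with estimated correlation). Examples are Cyp7b1 at -2.93 ± 0.32, Selenbp2 at -2.29 ± 0.26, Acot3 at -4.04 ± 0.28 and Cyp2b9 at -2.31 ± 0.17. Without 24 h replicate 1, 3 male-biased and 7 female-biased genes fell.

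Acute phase, interferon and cell cycle genes rose. Of 22 acute phase genes, 14 rose, 1 fell and 7 did not pass (16 and 3 adjusted over the list alone). The median was 0.97 (adjusted p = 1.7e-06, or p = 0.178 with estimated correlation). Cd14, a receptor for bacterial lipopolysaccharide, stood at 67.3 ± 10.9 against 4.68 ± 0.382 CPM, and the serum amyloid gene Saa3 rose by 6.71 ± 0.32. Of 23 interferon response genes, 17 rose and 6 did not pass (18 adjusted over the list alone). The median was 1.59 (adjusted p = 8.2e-08, or p = 0.321 with estimated correlation). The chemokine gene Cxcl10 rose by 5.20 ± 0.19 and Oasl2 by 3.70 ± 0.35. Of 26 cell cycle genes, 21 rose and 5 did not pass (21 adjusted over the list alone). The median was 2.20 (adjusted p = 4.9e-09, or p = 0.313 with estimated correlation). The replication licensing genes Mcm6 and Mcm2 rose by 3.22 ± 0.32 and 4.07 ± 0.42. With 24 h replicate 1 left out, 10 interferon and 10 cell cycle genes rose, and without control replicate 2, 10 and 13. Of 21 actin and dedifferentiation genes, 19 rose and 2 did not pass (19 adjusted over the list alone). The median was 2.42 (adjusted p = 1.1e-19, or p = 0.178 with estimated correlation). The intermediate filament gene Vim rose by 3.96 ± 0.23. Of 17 p53 response genes, 10 rose, 3 fell and 4 did not pass (10 and 3 adjusted over the list alone). The median was 0.96 (adjusted p = 0.000569, or p = 0.245 with estimated correlation). The death receptor gene Tnfrsf10b rose by 4.04 ± 0.31 and Phlda3 by 5.34 ± 0.48, and fewer than 2 fell without 24 h replicate 1 or 2 or control replicate 1. Of 15 immediate early genes, 8 rose, 2 fell and 5 did not pass (8 and 2 adjusted over the list alone). The median was 0.70 (adjusted p = 0.000359, or p = 0.387 with estimated correlation). Ier3 rose by 3.54 ± 0.24 and Klf4 by 2.20 ± 0.19, and fewer than 2 fell without 24 h replicate 1 or 2 or control replicate 1. Of 17 oxidative stress genes, 5 rose, 4 fell and 8 did not pass (5 and 4 adjusted over the list alone). The median was -0.037 (adjusted p = 0.160). The median and the test of that list differed in sign, and 2 fell without 24 h replicate 1 or control replicate 1. The pentose phosphate enzyme gene G6pdx stood at 3.25 ± 0.31 and the glutathione transferase gene Gsta1 at 5.35 ± 0.51. Of 11 Notch pathway genes, 5 rose and 6 did not pass (5 adjusted over the list alone). The median was 1.58 (adjusted p = 0.0801). That list passed without 24 h replicate 2 (adjusted p = 0.0301). Of 17 endoplasmic reticulum stress genes, 2 rose, 1 fell and 14 did not pass (2 and 1 adjusted over the list alone). The median was 0.45 (adjusted p = 0.315). It passed without control replicate 2 (adjusted p = 0.0479, 5 higher), 4 were higher without 24 h replicate 2, and fewer than 2 without 24 h or control replicate 1. Of 14 circadian clock genes, 2 rose, 4 fell and 8 did not pass (6 and 4 adjusted over the list alone). The median was 0.33 (adjusted p = 0.776). Without 24 h replicate 1, 1 clock gene fell, and without 48 h replicate 1 or 2, 4 rose.

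Markers of non-parenchymal cells rose at the same time. Of 19 stellate cell and matrix genes, 15 rose and 4 did not pass (15 adjusted over the list alone). The median was 2.11 (adjusted p = 4.0e-11, or p = 0.237 with estimated correlation). The metalloproteinase inhibitor gene Timp1 rose by 6.41 ± 0.40 and Tagln, an actin-binding protein gene with an antisense neighbour over 67.9% of its exons, by 3.65 ± 0.30. Of 19 macrophage genes, 13 rose and 6 did not pass (15 adjusted over the list alone). The median was 1.77 (adjusted p = 2.1e-08, or p = 0.245 with estimated correlation). Cd68 rose by 2.71 ± 0.16 and Gpnmb, a glycoprotein of macrophages, by 5.24 ± 0.45, and 8 of the list rose without 24 h replicate 1. Of 18 endothelial genes, 12 rose and 6 did not pass (12 adjusted over the list alone). The median was 0.97 (adjusted p = 0.000331, or p = 0.396 with estimated correlation). Stab1 rose by 1.54 ± 0.16 and Cdh5 by 2.02 ± 0.26, and 6 of the list rose without 24 h replicate 1 or control replicate 2. Of 6 neutrophil genes, 5 rose and 1 did not pass (5 adjusted over the list alone). The median was 4.18, or 3.52 with the 2 genes absent from a group at their lower bound (adjusted p = 0.000331, or p = 0.178 with estimated correlation). The interleukin gene Il1b rose by 3.87 ± 0.29, and S100a9 stood at 2.74 ± 0.379 CPM with no read in either control. Without 24 h replicate 1 or control replicate 1 or 2, 3 neutrophil genes rose. Of 17 biliary and progenitor genes, 8 rose and 9 did not pass (8 adjusted over the list alone). The median was 1.12 (adjusted p = 0.0219, or p = 0.418 with estimated correlation). Bicc1 rose by 1.48 ± 0.21 and the progenitor factor gene Sox9 by 1.89 ± 0.32. The biliary call was lost without control replicate 1 (adjusted p = 0.0711, 4 genes higher), and 5 were higher without 24 h replicate 1 or 2. Of 3 lymphocyte genes, 1 rose and 2 did not pass (none adjusted over the list alone). Of 2 red blood cell genes, Hbb-bs rose by 2.90 ± 0.84 and Alas2 did not pass, at -0.34 ± 0.50 (1 adjusted over the list alone). Hbb-bs lost its call without 24 h replicate 2 or either control (adjusted p = 0.107 to 0.150), and Alas2 turned positive without 24 h replicate 1 (0.22) or control replicate 1 (0.016). The 1 sex chromosome transcript tested did not pass by edgeR or DESeq2.

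Beside Afp, the largest rises among named genes were those of Mmp12, a macrophage elastase, at 7.23 ± 0.77 (12.29 and 6.23 without control replicates 1 and 2), the endothelial adhesion gene Sele at 7.19 ± 0.44 and the growth factor gene Igf2 at 7.04 ± 1.43. Igf2 shares 62.8% of its exon length with another gene, rose by 4.37 without 24 h replicate 1 and 8.10 without control replicate 2, and lost its call without control replicate 1 (adjusted p = 0.0597). The largest falls were of pancreatic enzyme genes: Pnlip at -12.63 ± 2.81, Cpb1 at -10.97 ± 2.60, Ctrb1 at -10.59 ± 2.50 and Cela2a at -10.41 ± 2.48. Their control level came mostly from 1 library, with Pnlip at 1457 RPM in control replicate 1 and 10.7 RPM in control replicate 2, and without control replicate 1 they stood at -6.56, -4.94, -4.44 and -4.55, and without control replicate 2 at -13.64 to -11.41. All 4 calls were lost without 24 h replicate 1 or 2 (adjusted p = 0.0862 to 0.0958 for Pnlip, 0.0961 to 0.110 for Cpb1, 0.0870 to 0.115 for Ctrb1 and 0.0958 to 0.110 for Cela2a). Akt1 rose by 0.35 ± 0.10, a call lost with any 1 of the 6 libraries left out (adjusted p = 0.0759 to 0.153), and Notch1 did not pass, at -0.45 ± 0.17. Of all calls at 24 h, 51.0% were higher with TMM, 83.3% without scaling factors and 62.8% with upper-quartile scaling, which shifted the median of all genes by 0.15 relative to TMM. With 24 h replicate 1 left out, 1442 genes were higher and 1379 lower.

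At 48 h after TAA, livers held more cell cycle, macrophage and matrix transcripts and fewer pericentral transcripts than control livers (n = 2 each). Gpnmb went from 0.202 to 139.6 ± 5.03 CPM, a log2 fold change of 9.36 ± 0.45 (adjusted p = 0.000113). Foxm1 rose by 5.997 ± 0.39 to 29.9 CPM, and the collagen gene Col1a2 stood at 279 ± 71.0 against 7.33 ± 1.44 CPM. Cyp2e1 was at 99.3 ± 15.1 against 5347 ± 1595 CPM, and Ctgf went from 3.16 to 71.7 CPM. In all, 3372 of 13497 genes were higher and 3226 lower at an adjusted p under 0.05, of which 2675 and 1489 moved at least 2-fold.

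Of 21 YAP/TAZ target genes, 11 rose, 2 fell and 8 did not pass (13 and 2 adjusted over the list alone). The median was 1.85 (adjusted p = 7.7e-06, or p = 0.213 with estimated correlation). Ctgf rose by 4.50 ± 0.27, Myof by 5.60 ± 0.22, Ankrd1 by 3.92 ± 0.31 and Ccdc80 by 3.16 ± 0.26. Cyr61, at 115 ± 47.5 against 81.0 ± 0.383 CPM, did not pass (adjusted p = 0.156), and Wwtr1 rose by 0.89 ± 0.16. Yap1 at -0.11 ± 0.12 and Lats1 at -0.048 ± 0.11 did not pass and turned positive with upper-quartile scaling (0.053 and 0.12), and Lats2 did not pass, at 0.36 ± 0.19. Of 22 Hippo pathway components, 9 rose, 3 fell and 10 did not pass (10 and 3 adjusted over the list alone). The median was 0.28 (adjusted p = 0.231). Ajuba rose by 1.61 ± 0.17 and Map4k4 by 1.55 ± 0.19. Of 11 Notch pathway genes, 6 rose and 5 did not pass (6 adjusted over the list alone). The median was 0.97 (adjusted p = 0.0751). The ligand gene Jag1 rose by 1.98 ± 0.20 and Lfng by 3.30 ± 0.45, and 3 of the list rose without control replicate 1. Notch1 at -0.095 ± 0.17 and Akt1 at 0.30 ± 0.10 did not pass, and Notch1 turned positive without 48 h replicate 2 (0.062) and with upper-quartile scaling (0.069).

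All 26 cell cycle genes rose (26 adjusted over the list alone). The median was 5.19 (adjusted p = 6.9e-21, or p = 0.213 with estimated correlation). Mcm6 rose by 4.25 ± 0.33. All 19 macrophage genes rose (19 adjusted over the list alone). The median was 2.97 (adjusted p = 3.9e-16, or p = 0.213 with estimated correlation). Cd68 stood at 76.4 ± 1.42 against 4.53 ± 0.738 CPM. Of 19 stellate cell and matrix genes, 16 rose and 3 did not pass (17 adjusted over the list alone). The median was 2.76 (adjusted p = 4.0e-16, or p = 0.213 with estimated correlation). Timp1 rose by 6.995 ± 0.39 and Col1a2 by 5.25 ± 0.26. Of 18 endothelial genes, 14 rose and 4 did not pass (14 adjusted over the list alone). The median was 1.13 (adjusted p = 0.000321, or p = 0.344 with estimated correlation). Stab1 rose by 2.05 ± 0.16 and the co-receptor gene Eng by 1.85 ± 0.23, and 8 of the list rose without control replicate 2. All 6 neutrophil genes rose (6 adjusted over the list alone). The median was 5.16, or 3.17 with the 2 genes absent from a group at their lower bound (adjusted p = 0.00201, or p = 0.213 with estimated correlation). Il1b rose by 2.96 ± 0.28 and the receptor gene Csf3r by 3.37 ± 0.44. Of 17 biliary and progenitor genes, 7 rose, 1 fell and 9 did not pass (7 and 1 adjusted over the list alone). The median was 1.16 (adjusted p = 0.0122, or p = 0.393 with estimated correlation). The phosphoprotein gene Spp1 rose by 2.19 ± 0.22 and Bicc1 by 2.08 ± 0.21. Of 3 lymphocyte genes, 1 rose and 2 did not pass (2 adjusted over the list alone). Neither of 2 red blood cell genes passed by edgeR, but 1 did at an unadjusted p under 0.05 and 1 by DESeq2, and the 1 sex chromosome transcript tested passed by neither.

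All 14 pericentral genes fell (14 adjusted over the list alone). The median was -2.81 (adjusted p = 5.4e-11, or p = 0.213 with estimated correlation). Cyp2e1 stood at -5.75 ± 0.32. Of 15 periportal genes, 10 fell and 5 did not pass (10 adjusted over the list alone). The median was -1.30 (adjusted p = 9.7e-05, or p = 0.213 with estimated correlation). Pigr stood at -3.57 ± 0.18 and Cyp2f2 at -2.18 ± 0.19. Of 20 hepatocyte identity genes, 14 fell and 6 did not pass (15 adjusted over the list alone). The median was -1.23 (adjusted p = 1.0e-06, or p = 0.213 with estimated correlation). The hepatocyte regulator gene Cebpa was at 126 ± 5.17 against 351 ± 9.51 CPM and F9 at -1.59 ± 0.12. Of 20 cholesterol synthesis genes, 19 fell and 1 did not pass (19 adjusted over the list alone). The median was -1.56 (adjusted p = 9.3e-07, or p = 0.330 with estimated correlation). The mevalonate pathway gene Pmvk stood at -1.98 ± 0.22. Of 15 fatty acid synthesis genes, 13 fell and 2 did not pass (14 adjusted over the list alone). The median was -2.03 (adjusted p = 4.1e-09, or p = 0.235 with estimated correlation). Acacb stood at -3.12 ± 0.13 and Mlxipl at -2.26 ± 0.18. Of 17 fatty acid oxidation genes, 15 fell and 2 did not pass (15 adjusted over the list alone). The median was -1.37 (adjusted p = 0.000151, or p = 0.213 with estimated correlation). Etfdh stood at -1.37 ± 0.15. Of 17 bile acid genes, 14 fell and 3 did not pass (14 adjusted over the list alone). The median was -2.34 (adjusted p = 9.6e-10, or p = 0.213 with estimated correlation). Baat stood at -2.57 ± 0.12 and Cyp27a1 at -3.93 ± 0.23. Of 10 male-biased liver genes, 1 rose, 7 fell and 2 did not pass (1 and 8 adjusted over the list alone). The median was -1.40 (adjusted p = 0.0255, or p = 0.213 with estimated correlation). Of 12 female-biased liver genes, 10 fell and 2 did not pass (10 adjusted over the list alone). The median was -2.81 (adjusted p = 8.1e-06, or p = 0.213 with estimated correlation). Examples are Cyp7b1 at -2.35 ± 0.31, Selenbp2 at -1.85 ± 0.25, Cyp2b9 at -2.18 ± 0.17 and Cyp2b13 at -2.27 ± 0.20, and 4 male-biased genes fell without 48 h replicate 2.

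Of 21 actin and dedifferentiation genes, 18 rose and 3 did not pass (19 adjusted over the list alone). The median was 2.81 (adjusted p = 6.2e-24, or p = 0.213 with estimated correlation). Anxa2 stood at 319.8 ± 2.37 against 5.85 ± 0.621 CPM and the calcium-binding S100a11 rose by 5.55 ± 0.24. Of 23 interferon response genes, 17 rose and 6 did not pass (20 adjusted over the list alone). The median was 1.97 (adjusted p = 8.8e-07, or p = 0.330 with estimated correlation). Cxcl10 rose by 3.10 ± 0.18 and Oasl2 by 4.84 ± 0.35. Of 17 p53 response genes, 11 rose, 2 fell and 4 did not pass (11 and 3 adjusted over the list alone). The median was 1.05 (adjusted p = 0.00487, or p = 0.301 with estimated correlation). Phlda3 rose by 6.11 ± 0.47 and Tnfrsf10b by 4.32 ± 0.31. Of 22 acute phase genes, 6 rose, 4 fell and 12 did not pass (6 and 4 adjusted over the list alone). The median was 0.23 (adjusted p = 0.0800). Cd14 rose by 3.99 ± 0.18 and Saa3 by 3.86 ± 0.28, the list passed without control replicate 2 (adjusted p = 0.0367, 7 lower), and 2 were lower without 48 h replicate 2. Of 15 immediate early genes, 6 rose and 9 did not pass (6 adjusted over the list alone). The median was 0.29 (adjusted p = 0.0439, or p = 0.505 with estimated correlation). Their call was lost without 24 h replicate 1 or 2, 48 h replicate 2 or control replicate 1 (adjusted p = 0.0693, 0.0641, 0.160 and 0.149), and 2 fell without control replicate 1. Of 17 oxidative stress genes, 8 rose, 5 fell and 4 did not pass (8 and 5 adjusted over the list alone). The median was 0.16 (adjusted p = 0.0910). The haem oxygenase gene Hmox1 rose by 2.77 ± 0.18 and the cystine transporter gene Slc7a11 by 7.12 ± 0.65 (9.77 without control replicate 1), and 3 of the list fell without 48 h replicate 2. Of 17 endoplasmic reticulum stress genes, 2 rose, 3 fell and 12 did not pass (2 and 2 adjusted over the list alone). The median was -0.29 (adjusted p = 0.589). Only 1 of them fell without 48 h replicate 1 or 2 or control replicate 2. Of 14 circadian clock genes, 1 rose, 4 fell and 9 did not pass (1 and 4 adjusted over the list alone). The median was -0.12 (adjusted p = 0.474). The mean of the clock genes was 0.020, of the other sign, and 1 of them fell without 48 h replicate 1.

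Other large rises among named genes at 48 h were Afp at 9.09 ± 0.55, Mmp12 at 8.38 ± 0.78 and the regenerating protein gene Reg2 at 7.87 ± 1.57, which lost its call without control replicate 2 (adjusted p = 0.0628). Without control replicates 1 and 2 in turn, Mmp12 stood at 13.40 and 7.34 and Reg2 at 12.33 and 6.84, and Reg2 at 5.34 without 48 h replicate 2. The largest falls were Hamp2, a relative of the iron hormone hepcidin, at -6.56 ± 0.62, and the cytochrome genes Cyp2c38 at -6.50 ± 0.23, Cyp3a16 at -6.36 ± 1.22 and Cyp3a41b at -6.20 ± 1.04, from gene families that may share reads, the last 2 at -8.40 and -8.22 without 48 h replicate 1. Of all calls at 48 h, 51.1% were higher with TMM, 88.8% without scaling factors and 62.4% with upper-quartile scaling, which shifted the median of all genes by 0.16 relative to TMM. Without 48 h replicates 1 and 2 in turn, 2077 and 2011 genes were lower.

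**Figure D3:**
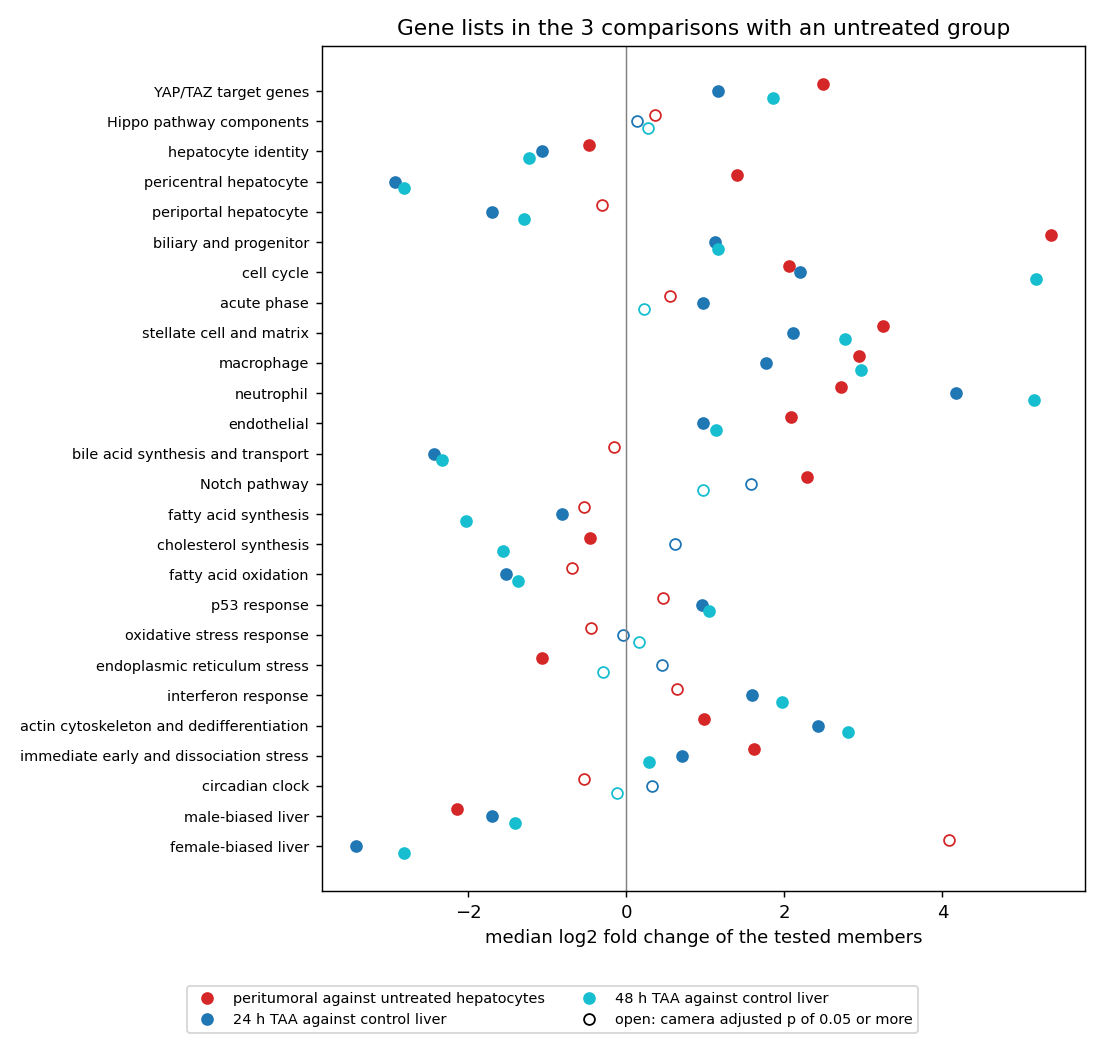
Median log2 fold change (horizontal axis) of each list tested in all 3 comparisons with an untreated group, with 1 point per list and comparison, filled where the camera adjusted p with the preset correlation is under 0.05. The YAP/TAZ target list lies at 2.49, 1.16 and 1.85, and the pericentral list at 1.40 in peritumoral hepatocytes and at -2.92 and -2.81 after TAA.

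Between 24 h and 48 h, cell cycle and macrophage genes were higher and cholesterol synthesis genes lower (n = 2 each, tested directly). Foxm1 went from 2.07 ± 0.498 to 29.9 ± 10.2 CPM, a log2 fold change of 3.84 ± 0.32 (adjusted p = 0.0109). Of 26 cell cycle genes, 15 rose and 11 did not pass (18 adjusted over the list alone). The median was 2.75 (adjusted p = 1.4e-24, or p = 0.341 with estimated correlation). Of 20 cholesterol synthesis genes, 17 fell and 3 did not pass (20 adjusted over the list alone). The median was -2.08 (adjusted p = 3.0e-30, or p = 0.341 with estimated correlation). Of 21 YAP/TAZ target genes, 6 rose and 15 did not pass (6 and 2 adjusted over the list alone). The median was 0.30 (adjusted p = 0.00346, or p = 0.354 with estimated correlation). Of 19 macrophage genes, 8 rose and 11 did not pass (15 adjusted over the list alone). The median was 1.28 (adjusted p = 1.4e-15, or p = 0.341 with estimated correlation). Of 19 stellate cell and matrix genes, 6 rose and 13 did not pass (9 adjusted over the list alone). The median was 0.92 (adjusted p = 4.3e-09, or p = 0.354 with estimated correlation). Of 21 actin and dedifferentiation genes, 9 rose and 12 did not pass (10 and 2 adjusted over the list alone). The median was 0.76 (adjusted p = 1.3e-09, or p = 0.341 with estimated correlation). Of 22 acute phase genes, 6 fell and 16 did not pass (10 adjusted over the list alone). The median was -0.70 (adjusted p = 9.6e-08, or p = 0.301 with estimated correlation). Of 15 fatty acid synthesis genes, 7 fell and 8 did not pass (11 adjusted over the list alone). The median was -1.10 (adjusted p = 1.0e-10, or p = 0.354 with estimated correlation). Of 17 fatty acid oxidation genes, 2 rose and 15 did not pass (2 adjusted over the list alone). The median was 0.17 (adjusted p = 0.0297, or p = 0.625 with estimated correlation). Of 17 endoplasmic reticulum stress genes, 1 rose, 1 fell and 15 did not pass (1 and 5 adjusted over the list alone). The median was -0.68 (adjusted p = 0.0129, or p = 0.834 with estimated correlation). The oxidation and reticulum stress calls were lost without 24 h replicate 1 (adjusted p = 0.148 and 0.151) or 48 h replicate 1 (0.0816 and 0.0760). Without either 24 h library at most 1 gene of any list passed, and without 48 h replicate 1, 2 cell cycle, 2 macrophage, 2 stellate and 2 YAP/TAZ target genes and at most 1 of any other list did. With 48 h replicate 2 left out, 5 macrophage, 5 actin, 3 stellate, 3 fatty acid synthesis, 2 YAP/TAZ target and 1 acute phase genes passed. With either control left out, 13 macrophage and 10 stellate genes rose and 2 YAP/TAZ target genes fell.

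The other lists did not pass between the times. No member passed by edgeR in the Hippo component (3 unadjusted, 1 by DESeq2, adjusted p = 0.801), hepatocyte identity (3 unadjusted, 4 by DESeq2, 0.0965), endothelial (3 unadjusted, 1 by DESeq2, 0.527), Notch (3 unadjusted, 0 by DESeq2, 0.752) and circadian clock lists (5 unadjusted, 2 by DESeq2, 3 adjusted over the list alone, 0.0928). Nor did any of 3 lymphocyte (2 unadjusted, 0 by DESeq2, 2 adjusted over the list alone), 2 red blood cell or 1 sex chromosome genes pass by edgeR, the latter also unadjusted or by DESeq2. In the others, members that passed, with in parentheses the counts adjusted over the list alone and the adjusted p, were pericentral 4 fell (5, 0.152), periportal 1 rose and 2 fell (1 and 2, 0.942), biliary 1 rose and 1 fell (2 and 1, 0.481), neutrophil 1 rose (2 and 2, 0.942), bile acid 1 rose and 3 fell (4 and 4, 0.990), p53 response 1 rose (1, 0.895), oxidative stress 3 rose and 1 fell (5 and 2, 0.527), interferon 1 rose and 1 fell (4 and 2, 0.752), immediate early 1 fell (2, 0.0687), male-biased 1 fell (1, 0.810) and female-biased 1 rose (1, 0.658). The pericentral, neutrophil, bile acid, p53 and male-biased lists had a median and a test or mean of different sign. Lists that passed with 1 library left out were identity without 24 h replicate 1 or 48 h replicate 2 (0.0284 and 0.0414), pericentral without 24 h replicate 2 or 48 h replicate 1 (0.0467 and 0.0305) and interferon without 24 h replicate 1 (0.00214). Immediate early genes did so without 48 h replicate 2 or control replicate 1 or 2 (0.00151, 0.00442 and 0.00491), and clock and female-biased genes without 48 h replicate 2 (0.0414 and 0.0389). Without 48 h replicate 2, 2 interferon genes fell, and at most 1 gene rose and 1 fell in each other list of this paragraph. With either control left out, 2 pericentral, 3 oxidative stress, 2 clock and 2 immediate early genes fell and 2 interferon genes rose, and without control replicate 1, 2 biliary genes rose.

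In all, 670 genes were higher and 319 lower at 48 h than at 24 h (67.7% higher, or 87.6% without scaling factors), of which 575 and 139 moved at least 2-fold. The largest changes named were the pancreatic enzyme genes Pnlip at 13.07 ± 2.84 and Cpb1 at 11.57 ± 2.63, and downwards the ribonuclease gene Ang at -3.82 ± 0.45, which shares 18.2% of its exon length with Rnase4, and Hamp2 at -3.29 ± 0.55. Without 24 h replicate 1, 0 genes were higher and 2 lower by edgeR (2413 at an unadjusted p under 0.05), and without 24 h replicate 2 none passed (2777 unadjusted). Without 48 h replicate 1, 21 were higher and 5 lower, without 48 h replicate 2, 196 and 60, and without control replicates 1 and 2, 508 and 505 were lower. DESeq2 was not run without a library. Calls on Pnlip, Cpb1, Ang, Hamp2 and Foxm1 were lost without 24 h replicate 1 (adjusted p = 0.234, 0.248, 0.0931, 0.115 and 0.0901) or 24 h replicate 2 (0.208, 0.216, 0.0913, 0.112 and 0.0913). Without 48 h replicate 1 those on Pnlip, Cpb1 and Hamp2 were lost (0.122, 0.139 and 0.153), and without 48 h replicate 2 those on Pnlip, Cpb1 and Hamp2 (0.109, 0.123 and 0.0803).

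Peritumoral hepatocytes and injured livers shared higher genes. Of 12847 genes tested in both, 1141 were higher in peritumoral hepatocytes and at 24 h after TAA, where independent lists would share 483, and 1622 were higher in peritumoral hepatocytes and at 48 h, against 554. Ctgf, Ankrd1, Wwtr1 and Foxm1 were higher in all 3 comparisons. Camera called the macrophage, endothelial and stellate lists higher in each, calls lost with an estimated correlation. Lower genes overlapped less, with 175 shared with 24 h, where independent lists share 284, and 340 with 48 h, against 336. Across genes, which are not independent replicates, log2 fold changes correlated with a Pearson r of 0.34 and a Spearman rho of 0.27 for 24 h, and 0.50 and 0.41 for 48 h. Shared higher genes with 24 h numbered 642 without 24 h replicate 1, 747 without control replicate 2, and 686 and 734 without untreated replicates 1 and 2. Those with 48 h numbered 946 and 1017 without untreated replicates 1 and 2. Shared lower genes with 24 h numbered 52 and 89 without 24 h replicates 1 and 2, 6, 26 and 85 without untreated replicates 1, 2 and 3, and 106 and 74 without peritumoral replicates 2 and 3. Those with 48 h numbered 160 and 154 without 48 h replicates 1 and 2, 11, 34 and 203 without untreated replicates 1, 2 and 3, and 192 and 109 without peritumoral replicates 2 and 3. The 24 h and 48 h comparisons shared 2297 higher and 2280 lower genes, against 719 and 661 for independent lists, or 1303 and 1308 without 24 h replicate 1. Both used the same 2 controls: unchanged groups simulated against these gave an r of 0.567, where the data gave 0.824, a covariance of 0.155 against 2.11 observed, a difference of 1.96, and 0.30 shared higher and 0 shared lower genes on average. With 1 control of its own for each time, in either assignment, they shared 1403 or 1606 higher genes, against 418 or 419.8 for independent lists, and 1785 or 1753 lower genes, against 521 or 502, with a covariance of 1.95 or 2.32.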

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

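All tests in this part were chosen only after the result was seen, except the test for acinar tissue and those between 24 h and 48 h. No group held 4 or more libraries, so no library was tested for standing far from the others of its group. Livers at 48 h and 24 h differed by the direct test: 670 genes were higher and 319 lower at 48 h, although without 24 h replicate 1 only 0 and 2 passed by edgeR (2413 at an unadjusted p under 0.05), and none without 24 h replicate 2 (2777 unadjusted). DESeq2 called 1006 and 539 with every library. List medians at 48 h against 24 h were 0.30 for YAP/TAZ target, 2.75 for cell cycle, -0.70 for acute phase, 0.92 for stellate and matrix, 1.28 for macrophage, -1.10 for fatty acid synthesis, -2.08 for cholesterol synthesis, 0.17 for fatty acid oxidation, -0.68 for endoplasmic reticulum stress and 0.76 for actin genes, and each call was lost with an estimated correlation. The log2 fold changes of the genes named there were 13.07 for Pnlip, 11.57 for Cpb1, -3.82 for Ang, -3.29 for Hamp2 and 3.84 for Foxm1, and all 5 calls were lost without either 24 h library (adjusted p = 0.0901 to 0.248), as were those on the oxidation and reticulum stress lists without 24 h replicate 1 (0.148 and 0.151) or 48 h replicate 1 (0.0816 and 0.0760).

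Biliary and Notch genes stood higher in peritumoral replicate 2 than in replicates 1 and 3, by a median log2 ratio of 2.29 (bootstrap SE 0.168, 28 genes), and Xist was at 527 RPM there and at most 0.183 RPM in the other hepatocyte libraries. A lower share of hepatocytes would raise every other cell type alike, and endothelial genes, at -0.87 (SE 0.0703), argue against it. Female sex may contribute: livers with Xist exceeded untreated hepatocytes with Y transcripts by 0.26 (SE 0.262) in biliary and Notch genes. Stock differs there, preparation may differ and sex is tied to 1 library, so it cannot be told apart. Tumour cells with injected sequences stay open. Akt1, at 1.02, lay within the spread of tested genes (percentile 89.2), and Notch1, at 2.18 (96.9), is part of the pattern. Injury or another response of tissue around tumours stays open, untested.

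YAP/TAZ target genes were higher in peritumoral hepatocytes together with macrophage, endothelial, stellate and biliary genes. Macrophages as the single source cannot be told apart: their markers and the target genes differed by median log2 ratios of 1.43 and 0.26 between peritumoral replicates 3 and 1, but 0.54 and 0.25 between 2 and 1, a gap within 2 SE of 0 (0.29, SE 0.245). Nor can endothelial cells alone, at 1.13 and -0.27 between 3 and 2 but 0.61 and 0.26 between 3 and 1 (gap 0.34, SE 0.225), since these are single libraries. A mixture of other cells could account for the rise, since stellate and matrix genes rose by a median of 3.25 while the target genes rose by 2.49, and it cannot be told apart from a change within hepatocytes because these are bulk libraries. The split into groups was 1 of 10 possible splits of the 6 libraries, too few for a share under 0.05, and called 3930 genes (1359 and 1494 without untreated replicates 1 and 2) where the highest of the others called 1.

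Pancreatic enzyme transcripts were high in control liver replicate 1 and both 48 h libraries, where 23 acinar genes summed to 8752, 4470 and 17930 RPM, against 72.5 RPM in control replicate 2 and 8.78 and 7.23 RPM at 24 h. All 11 acinar genes that had not been looked at before were at least 10 times their 24 h level in control replicate 1, consistent with acinar tissue in the preparation. A response to TAA is argued against by the 8752 RPM in control replicate 1, which had no TAA. Between 48 h replicate 2 and control replicate 1 the genes differed by a median log2 ratio of 1.07 with an SD of 0.316. The hepatocyte libraries held 17.2 to 329 RPM of these genes.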

How the results depend on the processing

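The tests on the genes of the authors' RPM table, without the doubted hepatocyte libraries, of lists and overlaps with a library left out, without scaling factors, of separate controls for the 2 times, and the alternatives to the planned test of the YAP/TAZ target list between these were chosen after seeing the data. Called genes named in the 4 comparisons (peritumoral, 24 h, 48 h, and 48 h against 24 h) numbered 42, 58, 53 and 5, none of which turned direction under any setting. Of them, 35, 42, 45 and 2 kept their call in every setting that left no library out, and 28, 50, 52 and 0 with each library left out. A group left with 1 library is assumed to vary like the others. RLE factors and the legacy and robust dispersion estimates moved no gene count by over 1.5 times. Where a count below moved, the cause was not tested, except that stricter thresholds call fewer genes by construction, fewer libraries give less power, and the limma counts lie near those without scaling factors in livers.

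Among peritumoral changes, 1211 genes were higher and 97 lower at an adjusted p under 0.01. The lower genes numbered 371 with a change of at least 2-fold, 673 with upper-quartile factors, 819 with a filter of 50 counts, 2354 with all 12 libraries in 1 fit and 2382 without both doubted libraries. By limma on log2(RPM + 0.5) and log2(RPM + 0.1) they numbered 155 and 204. With each library left out, 1293 to 2657 genes were higher and 66 to 1398 lower. At 24 h, 1381 were higher and 1481 lower at 0.01, 1372 fell at least 2-fold, and 1225 were lower with all 12 libraries. At 48 h these were 2229, 1930, 1489 and 1698. By limma with the 2 pseudocounts, 6113 and 6300 genes were higher and 1203 and 1205 lower at 24 h, and 8178 and 8231 higher and 1008 and 991 lower at 48 h. The RPM table carries no TMM factors, which are near 0.75 in the controls and over 1 after TAA. By edgeR without scaling factors, 205 genes were lower in peritumoral hepatocytes, 6127 were higher and 1228 lower at 24 h, 7661 and 971 at 48 h, and 1281 and 181 at 48 h against 24 h. With each library left out, 1442 to 2460 genes were higher and 1379 to 2389 lower at 24 h, and 2011 to 3141 lower at 48 h. At 48 h against 24 h, 7 were higher and 3 lower at 0.01, 139 fell at least 2-fold, 1006 were higher and 539 lower by DESeq2, 183 were lower without a filter, and 99 were higher and 32 lower with all 12 libraries. By limma 1353 were higher with a pseudocount of 0.5, and 182 and 141 lower with 0.5 and 0.1. With each library left out, 0 to 839 were higher and 0 to 508 lower by edgeR, and 2413 and 2777 genes had an unadjusted p under 0.05 without 24 h replicates 1 and 2.

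Replicate numbers recur in all groups, but no label says that they pair the libraries, and deviations of same-numbered hepatocyte libraries correlated at -0.28, 0.24 and 0.13, so they share only a number. Untreated replicates 1 to 3 correlated best with peritumoral replicates 2, 2 and 1. In the livers, same-numbered libraries correlated at -0.025 (24 h and 48 h), 0.016 (24 h and control) and -0.047 (48 h and control). With the replicate block, 2237 peritumoral genes were higher and 709 lower, oxidative stress genes passed (camera adjusted p = 0.0479), immediate early genes did not at 48 h (0.0726) and did between the times (0.0262), and fatty acid oxidation genes did not between the times (0.0599). No other call on a list changed with it.

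With an estimated correlation, whose power was not measured here, each list called by camera lost its call. The YAP/TAZ target list had adjusted p = 0.107, 0.214, 0.213 and 0.354. At 48 h against 24 h it also lost it on the genes of the authors' table (0.0760), and by fry it (0.0659) and each other list called there but acute phase lost theirs (up to 0.422). In peritumoral hepatocytes 7 of 15 called lists lost it by fry (0.0511 to 0.197). Lists below the threshold whose test turned direction, all uncalled, had these adjusted p-values by fry: 0.981 for red blood cell genes in peritumoral hepatocytes, and between the times 0.886 for neutrophil, 0.755 for bile acid and 0.886 for p53 response genes. Camera with each library left out gave 0.272 to 0.864, 0.615 to 0.996, 0.417 to 0.908 and 0.295 to 0.908 for the same lists. It gave, in peritumoral hepatocytes, 0.0201 to 0.981 for periportal, 0.0628 to 0.782 for bile acid and 0.0117 to 0.589 for interferon genes, 0.537 to 0.933 for clock genes at 24 h and 0.308 to 0.758 for reticulum stress genes at 48 h. Between the times it gave 0.296 to 0.947 for periportal, 0.0652 to 0.871 for biliary, 0.0512 to 0.877 for endothelial, 0.355 to 0.888 for Notch, 0.168 to 0.926 for oxidative stress, 0.00214 to 0.871 for interferon, 0.385 to 0.855 for male-biased and 0.0389 to 0.775 for female-biased genes.

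Genes that turned direction had not been called. By limma with pseudocounts of 0.5 and 0.1, log2 fold changes were 0.012 and 0.012 for Lats1 in peritumoral hepatocytes, 0.45 and 0.45 for Lats1, 0.063 and 0.064 for Notch1 and 0.030 and 0.027 for Alas2 at 24 h, and 0.60 and 0.60 for Yap1, 0.66 and 0.66 for Lats1 and 0.60 and 0.61 for Notch1 at 48 h. Upper-quartile factors gave 0.090 for Lats1 at 24 h and 0.053, 0.12 and 0.069 for Yap1, Lats1 and Notch1 at 48 h. Lats1 stood at 0.057 and 0.031 at 24 h and 48 h with all 12 libraries and at 0.014 at 48 h with a filter of 50 counts. With each library left out, Lats2 ran from -0.10 to 0.42 and Alas2 from -1.27 to 0.22 at 24 h, and Notch1 from -0.27 to 0.062 at 48 h.

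Peritumoral hepatocytes shared 343 higher and 3 lower genes with 24 h at an adjusted p under 0.01, 25 lower genes at 2-fold, and 642 to 1149 higher and 6 to 187 lower genes with each library left out. With 48 h these numbers were 713, 9, 33, 946 to 1633 and 11 to 357. The 2 times after TAA shared 1148 higher and 1253 lower genes at 0.01, 1037 lower genes at 2-fold, and 1303 to 1835 higher and 1308 to 2064 lower genes with each library left out. They shared 1403 higher genes with 24 h against control replicate 1 and 48 h against control replicate 2.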

Other observations

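Values here were picked after being seen, with no test beyond those reported above. All 6 liver libraries held Xist, at 196 to 456 RPM, and no read of the Y-linked helicase gene Ddx3y. The hepatocyte libraries other than peritumoral replicate 2 held Ddx3y at 59.6 to 75.5 RPM. Peritumoral replicate 3 held Ddx3y at 62.1 RPM but little of Cyp4a12a, a cytochrome of male liver, at 0.672 RPM, where the untreated hepatocytes stood at 285 to 492 RPM and peritumoral replicate 1 at 345 RPM. The same library held 267 RPM of the steroid enzyme gene Cyp17a1, 144 RPM of A1bg and 294 RPM of Cyp3a44, the latter 2 typical of female liver.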
